A study of Arabidopsis thaliana with 18 samples.

How the data were processed

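Steady-state and polysome-bound RNA of Arabidopsis thaliana seedlings was measured on Affymetrix arrays. Per the labels' protocols, seeds of Col-0 were plated on MS agar, 4-day-old etiolated seedlings were kept dark or given white light, and aerial parts were used. Polysome RNA came from a sucrose gradient and was purified by phenol/chloroform extraction and lithium chloride precipitation, per the labels' protocols. Biotin-labelled cRNA was prepared by the array maker's standard method, per the labels' protocols. The 18 samples form 6 groups of 3: dark, 0.5 h and 4 h of light, each as steady-state and polysome RNA, and the labels call the replicates biological.

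The deposited values are linear signal intensity values made with MAS5, per the submitters' processing notes; its version and settings are not given in the sources used here. The deposited table holds 22810 probe sets, and its 2% trimmed mean lies between 500.04 and 500.05 in each array, so every array had been scaled to the same level. Of the 153 pairs of arrays, the highest share of equal signals was 0.285%. Array medians lay between 152.7 and 205.6. Detection calls were not used here. All-array scaling leaves only relative changes visible.

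From these values, 64 control probe sets were taken out, 915 values under 1 were raised to 1, and log2 was taken. Probe sets whose mean log2 signal over all arrays reached the 30th percentile were kept, 15922 in number, with a smallest geometric mean of 42.089. Gene names came from the array annotation, updated through a reference gene table: 13513 probe sets list 1 gene, 503 several and 8730 none, and of the tested ones 8788, 326 and 6808.

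The test was limma 3.58.1 in R 4.3.3, with 1 mean for each of 6 groups, moderated variances with an intensity trend, and a Benjamini-Hochberg adjusted p under 0.05 over the probe sets tested. Calls with a change of 2-fold or more were counted beside these. The comparisons were light against dark at 0.5 h and 4 h and 4 h against 0.5 h in each kind of RNA, polysome against steady-state RNA in each light condition, and the change of that ratio at 0.5 h and 4 h. Across probe sets the median standard error was 0.249, and 0.352 for changes in ratio.

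Gene lists, 26 in number, were written before the data were examined, from general knowledge, as were the comparisons, tests, filter, alternatives and the rule for genes to name. The chloroplast-encoded and mitochondrion-encoded lists were named then, and their members taken by chromosome from the reference gene table. That match found no mitochondrial gene, as the table's identifiers differ from the annotation's there, and the chloroplast list holds what the match found. Of these lists 13 had 3 or more measured genes and were tested with limma's camera, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A gene counts as measured where a tested probe set lists it alone. In most lists only a small part of the listed genes was measured, so a list result holds for its measured members. Counts of called members are given over all probe sets and adjusted over the list alone. Of 143 list tests, 18 had a median, mean or direction of differing sign, and the lowest adjusted p among these was 0.367. The rule for named genes took the 6 higher and 6 lower called genes of largest change whose groups do not overlap (3 and 3 for polysome against steady-state RNA and for 4 h against 0.5 h), from probe sets listing 1 gene. It added up to 3 members of each list by adjusted p, or the strongest signal where none passed, and HY5, TT4, LHCB1, ELIP1, PORA and PHYA. Other list members are named where they go against their list or are called in a short list.

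Replicate numbers pair the samples: over 9 compared pairs of groups, deviations from the group mean correlated at 0.108 to 0.426 for equal numbers and at most 0.0359 for different numbers. The basis of the pairing is not given in the sources used here; it comes from the data and from the numbers in the labels. A fit with the number as a block is therefore given beside the counts of calls and where it ended or gained the call of a list. Named genes that gained a call with it are counted at the end, some with their values.

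The alternatives were the compared arrays alone, each array left out in turn, quantile normalization, a common median, an estimated correlation, no intensity trend, no filter, a stricter filter at the 50th percentile (11373 probe sets), 32 added to each signal, and the replicate block. Replicate-wise ratios, the block with an estimated correlation, and leave-one-out for the correlation of changes were added after the data were seen.

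The scripts were tested on simulated data. With 15922 simulated probe sets, the 0.5 h steady-state comparison recovered 1.49% of changes of log2 0.5, 49.3% of 1 and 78.8% of 2, with 1 false call. The 4 h ratio change recovered 0%, 8.96% and 59.1%, with 3 false calls, so small changes in ratio are mostly missed.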

Results

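The series asked how white light changes the transcripts that are present, and the transcripts that are on polysomes, when dark-grown Arabidopsis thaliana seedlings are brought into light. Aerial parts of 4-day-old etiolated seedlings of the accession Columbia were taken in the dark, or after white light (0.5 h or 4 h) of 70 to 80 micromoles per square metre per second. From each, total RNA gave the steady-state level, and RNA recovered from polysomes (transcripts loaded with several ribosomes, separated from the rest on a sucrose gradient) gave the polysome-bound level. The 6 groups held 3 arrays each, which the labels call biological replicates, so 18 arrays were compared. The median signal of an array lay between 153 and 206, and the number of arrays limits the precision of every value. Errors of log2 changes below are standard errors (SE) of the fit across all 18 arrays, errors of signals are SD, and n = 3 arrays per group throughout. That fit leaves out the pairing of arrays by replicate number, except where the block is named. Every array had been scaled to the same level, so a change in the total amount of RNA on polysomes would not be visible.

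**Figure D1:**
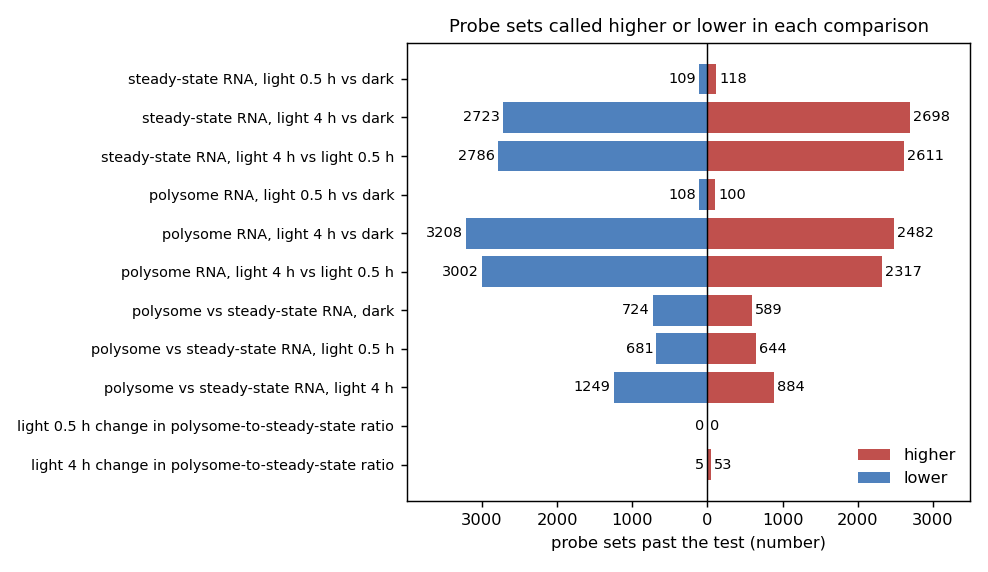
Number of probe sets (horizontal axis) called higher (red, right) or lower (blue, left) in each of 11 comparisons, out of 15922 tested. Comparisons of 4 h of light with dark or 0.5 h within a kind of RNA called 5319 to 5690, those of 0.5 h with dark 227 and 208, and those of polysome with steady-state RNA 1313 to 2133, and the change in the polysome-to-steady-state ratio called 0 at 0.5 h and 58 at 4 h.

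The comparison of 0.5 h of light with dark in steady-state RNA asked which transcripts respond first. STZ, which encodes a zinc-finger transcription factor, rose from a signal of 38.7 ± 6.92 to 261 ± 13.6, a log2 change of 2.77 ± 0.322 (adjusted p = 3.82e-05). IAA29, a member of the Aux/IAA repressors of auxin response, fell from 915 ± 243 to 145 ± 44.6, a log2 change of -2.67 ± 0.266 (adjusted p = 1.35e-05). UGT78D2, a flavonoid glycosyltransferase gene, rose from 85.8 ± 20.8 to 340 ± 107, by 1.97 ± 0.234 on the log2 scale (adjusted p = 4.9e-05). AT3G14200 rose by 2.34 ± 0.253 (adjusted p = 2.44e-05), AT1G66080 by 2.14 ± 0.36 and AT3G02910 by 2.04 ± 0.31. AT2G18010, AT4G36010 and AT1G54120 had log2 changes of -2.71 ± 0.412, -2.23 ± 0.279 and -1.99 ± 0.336 (highest adjusted p of the 3, 0.00191).

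In all, 227 of the 15922 probe sets changed, 118 higher and 109 lower, and 92 and 74 of them by 2-fold or more. With the replicate number as a block the count was 409 (197 higher, 212 lower). It was 147 without replicate 1 of the dark steady-state group, 389 (137 higher, 252 lower) without replicate 1 of the light 0.5 h steady-state group, and 88 in a fit of the 6 arrays compared alone, where AT1G66080 no longer passed (adjusted p = 0.0859).

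Calls of 5 further genes ended when single steady-state arrays were left out, which also leaves fewer arrays in the fit. AT5G63130 rose by 2.56 ± 0.52 (adjusted p = 0.0106), AT5G51440 by 2.14 ± 0.457 and AT5G12110, a subunit of translation elongation factor 1B, by 1.27 ± 0.299, while AT5G66330 and AT1G44830 changed by -2.34 ± 0.531 and -1.76 ± 0.438. The call of AT5G63130 ended without dark replicate 1 or 2 or light replicate 3 (highest adjusted p = 0.254), that of AT5G51440 without dark replicate 1 or light replicate 2 or 3 (0.184), and that of AT5G12110 without dark replicate 1 or 3 or light replicate 2 or 3 (0.332). For AT5G66330 it ended without any dark replicate or light replicate 3 (0.349), and for AT1G44830 without any of the 6 arrays (0.183). With 32 added to each signal before the log, the change of AT5G63130 was 1.53.

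Among the gene lists written before the data were examined, the 4 measured auxin-response and cell-elongation genes had a median log2 change of -0.48 at 0.5 h, with 1 gene (IAA29) lower, 0 higher and 3 not called (camera adjusted p = 0.000479; adjusted p = 0.0534 with an estimated correlation, and 0.025 when the replicate block was added). The 110 cytosolic ribosomal protein genes had a median of 0.11 with 0 genes called (adjusted p = 0.0388; adjusted p = 0.933 with an estimated correlation). That call ended without dark steady-state replicate 1 (adjusted p = 0.265) or 3 (0.245), or light 0.5 h steady-state replicate 2 (0.621) or 3 (0.223), with no filter (0.0639) and in the fit of the compared arrays alone (0.0602). For the 69 chloroplast-encoded genes, median -0.12 with 0 called (adjusted p = 0.0388; adjusted p = 0.933 with an estimated correlation), even the direction hung on single arrays. Their median was 0.14 without light 0.5 h steady-state replicate 1, 1.17e-06 without dark steady-state replicate 3, and -0.000244 without dark steady-state replicate 2 (adjusted p = 0.99), and the call also ended under quantile normalization (0.0779) and the stricter filter (0.059).

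None of the measured members of the light-harvesting, photosystem, chlorophyll, Calvin cycle, photorespiration, β-oxidation and starvation lists passed the test after 0.5 h in steady-state RNA, and the 7 list tests had adjusted p from 0.469 to 1 (limma and camera; 1232 of all probe sets had an unadjusted p under the threshold and 2017 with the block). The antenna gene LHCB4.1 changed by 0.03 ± 0.188 and the glyoxylate cycle gene ICL by -0.04 ± 0.197. HYH, the homologue of the light-signalling factor HY5, was at 0.82 ± 0.322 (adjusted p = 0.419), the 1 measured gene of its list. The small heat shock protein gene AT5G37670 was at 1.75 ± 0.447 (adjusted p = 0.0611, and 2.21e-05 with the block). The flavonoid list had 1 of 2 genes higher, and 2 when adjusted over the list alone.

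Polysome-bound RNA after 0.5 h of light was compared with polysome-bound RNA in the dark to see which early changes reach the ribosomes. STZ rose from 108 ± 48.8 to 556 ± 43.4, by 2.5 ± 0.322 on the log2 scale (adjusted p = 0.000146). IAA29 fell from 845 ± 169 to 131 ± 16.3, a log2 change of -2.67 ± 0.266 (adjusted p = 1.18e-05). AT3G14200 rose by 2.60 ± 0.253, AT3G02910 by 2.43 ± 0.31, AT2G19310 by 1.88 ± 0.344 and UGT78D2 by 1.39 ± 0.234 (highest adjusted p of the 4, 0.00414). AT2G18010, AT4G36010 and AT1G54120 changed by -2.31 ± 0.412, -2.04 ± 0.279 and -1.90 ± 0.336.

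Here 208 probe sets changed, 100 higher and 108 lower (74 and 79 by 2-fold or more), and 357 with the replicate block (174 and 183). The call of AT2G20560 (2.01 ± 0.405) ended without dark polysome replicate 1 or light 0.5 h polysome replicate 2 or 3, with adjusted p up to 0.0903. For AT4G27657 (1.74 ± 0.364) it ended without dark replicate 1 or 2 or light replicate 2 or 3 (0.106), and for AT5G12110 (1.29 ± 0.299) without any dark replicate or light replicate 2 or 3 (0.191). AT3G15570 (-3.05 ± 0.711, and -1.94 with 32 added to each signal) lost its call without any dark replicate or light replicate 3 (0.223), and AT1G44830 (-1.79 ± 0.438) without any dark replicate or light replicate 1 or 2 (0.374).

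The auxin list had a median of -0.51 in polysome RNA at 0.5 h, with 1 of 4 genes lower (camera adjusted p = 0.00122; adjusted p = 0.0757 with an estimated correlation, 0.0369 with the block added). The cytosolic ribosomal protein list had a median of 0.13 with 0 of 110 genes called (adjusted p = 0.00169; adjusted p = 0.747 with an estimated correlation); the call ended without dark polysome replicate 2 (0.0699) or 3 (0.4) or light 0.5 h polysome replicate 1 (0.804). The 10 nuclear-encoded plastid ribosomal protein genes had a median of 0.14, with 0 called and 1 higher when adjusted over the list alone (adjusted p = 0.0118; adjusted p = 0.606 with an estimated correlation). That call ended without dark polysome replicate 3 (0.124) or light 0.5 h polysome replicate 2 (0.142). The chloroplast-encoded list was at -0.11 (adjusted p = 0.155, and 0.0176 with the block; adjusted p = 0.747 with an estimated correlation), and AT5G37670 at 1.42 ± 0.447 (adjusted p = 0.228, and 0.000265 with the block).

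Across all probe sets, the 0.5 h changes in the 2 kinds of RNA, which share no array, had a Pearson r of 0.412 and a Spearman rho of 0.289 (across genes, which are not independent replicates). The size of r rests on the filter, at 0.131 with no filter and 0.663 with the stricter one. Of the calls, 81 probe sets were higher in both, where independent lists would share 0.741, and 77 were lower in both (0.739 for independent lists). STZ, AT3G14200 and UGT78D2 were among the former and IAA29 and AT2G18010 among the latter, and 0 were called in opposite directions. Steady-state and polysome arrays of equal number deviated together, with correlations of 0.295 to 0.377 in the dark and 0.186 to 0.348 at 0.5 h. The 2 lists are therefore not independent, and the counts for independent lists are only a reference.

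**Figure D2:**
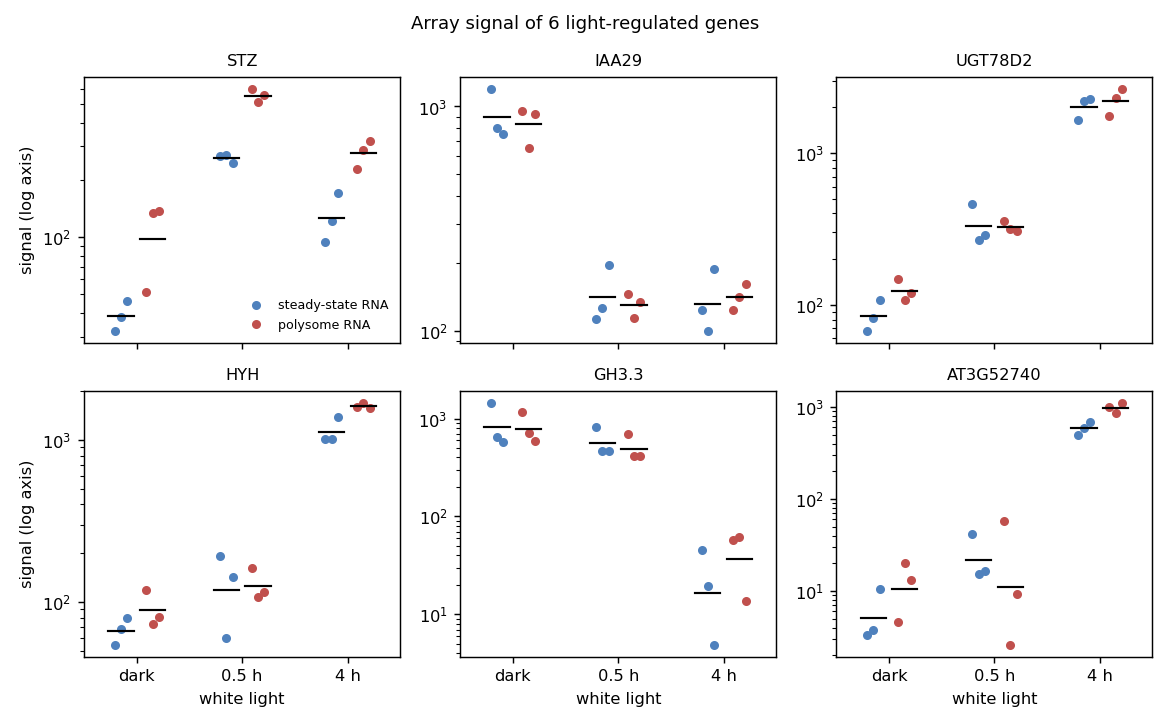
Array signal (vertical axis, log scale, arbitrary units) of 6 genes in the dark and after 0.5 h and 4 h of white light, for steady-state RNA (blue) and polysome RNA (red); each point is 1 array and the black line the geometric mean of 3. STZ is highest at 0.5 h, IAA29 is already low at 0.5 h, and UGT78D2, HYH and AT3G52740 are highest and GH3.3 lowest at 4 h.

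After 4 h of light, the comparison with dark in steady-state RNA covered a large part of the transcriptome. The methionine sulfoxide reductase gene MSRB6 rose from 104 ± 47.2 to 8880.4 ± 1272, a log2 change of 6.54 ± 0.331 (adjusted p = 1.79e-11). AT3G52740 (BIC1, an inhibitor of cryptochromes) rose from 5.9 ± 4.08 to 597 ± 97.2, by 6.86 ± 0.894 (adjusted p = 4.64e-06), and AT1G60590 by 6.62 ± 0.987. The thionin gene THI2.2, AT5G42760 and AT1G48100 rose by 6.53 ± 0.66, 6.17 ± 0.611 and 6.13 ± 0.648. AT5G02580 fell from 2147 ± 414 to 32.9 ± 26.3, a log2 change of -6.38 ± 0.521 (adjusted p = 8.86e-09), followed by AT2G34020 (-5.72 ± 0.467), AT4G25580 (-5.68 ± 0.528), the auxin-conjugating enzyme gene GH3.3 (-5.63 ± 0.625), AT2G19660 (-4.62 ± 0.264) and AT5G24580 (-4.60 ± 0.356). Changes from signals this low depend on the floor: with 32 added to each signal, that of AT3G52740 was 4.05, the smallest of these 6 rises, and that of MSRB6 6.1, the largest.

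In total 5421 probe sets changed, 2698 higher and 2723 lower, and 1660 and 1266 by 2-fold or more. With the replicate block the count was 6756 (3296 higher, 3460 lower).

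Most measured photosynthesis genes rose after 4 h in steady-state RNA, but few of those listed were measured. They were 6 of 34 photosystem and electron-transport, 3 of 21 antenna, 3 of 21 Calvin cycle and 4 of 15 photorespiration genes. The measured antenna genes were LHCB4 genes alone. All 6 measured nuclear photosystem and electron-transport genes were higher, with a median log2 change of 1.59 (camera adjusted p = 8.09e-05, and 0.0456 with an estimated correlation). Among them were PSBY (1.87 ± 0.151), PSAN (1.84 ± 0.213) and PSBW (1.36 ± 0.154). All 3 measured antenna genes rose (median 0.72, adjusted p = 0.0112; adjusted p = 0.0629 with an estimated correlation), LHCB4.3 from 251 ± 46.6 to 1549 ± 156, by 2.64 ± 0.181, and LHCB4.1 and LHCB4.2 by 0.72 ± 0.188 and 0.65 ± 0.184. All 3 measured Calvin cycle genes rose (median 1.85, adjusted p = 0.00197; adjusted p = 0.0629 with an estimated correlation): SBPASE by 1.98 ± 0.153, Rubisco activase (RCA) by 1.85 ± 0.157 to a signal of 25041 ± 1054, and PRK by 0.69 ± 0.183. Of 4 photorespiration genes 3 were higher, HPR by 1.98 ± 0.187 and the glycine cleavage genes AT1G11860 and AT1G32470 by 1.31 ± 0.185 and 0.96 ± 0.144. The other member, the glycerate kinase gene AT1G80380, was lower at -0.94, and the list as a whole did not pass (median 1.13, adjusted p = 0.0522; adjusted p = 0.227 with an estimated correlation).

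Among genes of chlorophyll synthesis in steady-state RNA at 4 h, HEME1 (uroporphyrinogen decarboxylase) rose by 1.93 ± 0.184 and the magnesium chelatase subunit gene CHLI2 by 1.86 ± 0.24, whereas the protochlorophyllide oxidoreductase gene PORB fell from 11179 ± 275 to 3416 ± 1024, a log2 change of -1.75 ± 0.205 (adjusted p = 1.2e-06). Of the 9 measured genes 5 were higher and 1 lower, or 6 and 1 adjusted over the list alone (median 0.79, camera adjusted p = 0.0142; adjusted p = 0.0866 with an estimated correlation). Both measured genes of the flavonoid list, which encode glycosyltransferases, rose, UGT78D2 by 4.58 ± 0.234 (adjusted p = 1.87e-11) and UGT78D1 by 4.30 ± 0.435, and HYH rose from 67.5 ± 12.6 to 1134 ± 216, by 4.07 ± 0.322.

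Measured auxin, starvation and reserve-mobilisation genes were mostly lower after 4 h in steady-state RNA. They were 4 of 24, 4 of 16 and 3 of 18 listed genes. All 4 measured auxin-response genes fell (median -2.28, camera adjusted p = 0.000493, and 0.0456 with an estimated correlation), with IAA29 at -2.76 ± 0.266 and WES1 at -1.81 ± 0.22 beside GH3.3. All 4 dark- and sugar-starvation-induced genes fell (median -2.02, adjusted p = 0.000108; adjusted p = 0.0629 with an estimated correlation). Among these were the leucine-breakdown genes MCCA, from 12050.1 ± 1460.5 to 1325 ± 417 (-3.22 ± 0.205), and IVD (-2.08 ± 0.189), and the kinase subunit gene AKINBETA1 (-1.96 ± 0.182). Isocitrate lyase (ICL) fell by 1.85 ± 0.197 and the oil-body lipase gene SDP1 by 0.93 ± 0.164, 2 of 3 genes in a β-oxidation and glyoxylate list with a median of -0.93 (adjusted p = 0.0457; adjusted p = 0.0866 with an estimated correlation, 0.0641 with the block). That list call also ended without dark steady-state replicate 1 (0.0866) or light 4 h steady-state replicate 3 (0.0673), under quantile normalization (0.0539), with the stricter filter (0.0771) and in the fit of the compared arrays alone (0.0624).

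Of the 110 cytosolic ribosomal protein genes, 44 were higher and 5 lower in steady-state RNA at 4 h, the same counts when adjusted over the list alone (median 0.36, camera adjusted p = 0.000493; adjusted p = 0.396 with an estimated correlation). AT3G10610 rose by 1.47 ± 0.207, AT4G30800 by 1.74 ± 0.276 and AT4G10450 by 1.31 ± 0.216, while the lower members were AT2G40010 (-1.15), AT3G14600 (-0.83), AT4G02230 (-0.54), AT3G02080 (-0.53) and AT5G35530 (-0.38). Of 10 plastid ribosomal protein genes 4 were higher, such as AT3G13120 (0.84 ± 0.155) and AT1G29070 (0.50 ± 0.131), and 1 lower, AT5G24490 (-1.64 ± 0.237), with adjusted p = 0.249 for the list. Of 7 translation factor genes 4 were higher, among them AT5G12110 (3.31 ± 0.299) and EIF4A-2 (0.85 ± 0.189), and 1 lower, AT5G19510 (-0.57 ± 0.162), whose call ended without dark steady-state replicate 2 or 3 (highest adjusted p = 0.0572). The translation factor list itself was at adjusted p = 0.0919.

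The smaller lists went different ways in steady-state RNA at 4 h. The 5 genes with conserved upstream reading frames (median -0.078, adjusted p = 0.706) held 1 higher, the polyamine-synthesis gene AT5G15950 (0.97 ± 0.219), and 1 lower, bZIP44 (-1.48 ± 0.23). Of the 69 chloroplast-encoded genes 5 were higher (2 adjusted over the list alone; adjusted p = 0.413 for the list), including psbC (1.3 ± 0.248), psbD (1.42 ± 0.294) and rbcL (0.73 ± 0.214), the last not called without light 4 h steady-state replicate 2 (adjusted p = 0.0852). The clock gene GI was higher by 0.86 ± 0.273 (adjusted p = 0.0186), a call that ended without dark steady-state replicate 2 or 3 or light 4 h steady-state replicate 1 (highest adjusted p = 0.101). STZ was still higher than in the dark, by 1.71 ± 0.322 (adjusted p = 0.000294). The DNA replication gene PRL was at 0.54 ± 0.28 (adjusted p = 0.155, and 0.0241 with the block), and AT5G37670 was back at 0.05 ± 0.447. Of the stomatal-lineage markers, SPCH rose from 27.5 ± 25.1 to 194 ± 51.7, by 3.17 ± 0.807 (adjusted p = 0.00424), while FMA was at -0.07.

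In polysome RNA, 4 h of light changed 5690 probe sets, 2482 higher and 3208 lower (1478 and 1398 by 2-fold or more). The replicate block called 7115 (3043 higher, 4072 lower). The median change over all probe sets was -0.0945, an offset that moved with the scaling and the filter. It was -0.0323 with a common median (2706 higher, 2796 lower; -0.0486 in steady-state RNA) and -0.0666 under quantile normalization (2597 higher, 2987 lower). With the stricter filter it was -0.144 and with no filter -0.0317. AT5G42760 rose from 32.1 ± 8.39 to 3849 ± 569, by 6.92 ± 0.611 (adjusted p = 2.6e-08), MSRB6 by 6.84 ± 0.331 to 12742 ± 2701, THI2.2 by 6.54 ± 0.66, AT3G52740 by 6.54 ± 0.894, AT3G57020 by 6.15 ± 0.339 and AT1G60590 by 6.13 ± 0.987. AT5G02580 fell from 2178 ± 202 to 27.8 ± 21.3, a log2 change of -6.62 ± 0.521, AT2G34020 was at -5.83 ± 0.467, AT2G19660 at -5.07 ± 0.264 and AT4G25580 at -4.78 ± 0.528. AT3G50120 (-5.11 ± 0.745) and AT4G25250 (-4.82 ± 0.598) were at -2.25 and -2.60 when 32 was added to each signal.

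Ribosomal protein genes were prominent on polysomes at 4 h: 78 of 110 cytosolic ones were higher and 1, AT2G40010, lower (84 and 1 adjusted over the list alone). Their median log2 change was 0.76 (camera adjusted p = 6.45e-17; adjusted p = 0.0676 with an estimated correlation), with AT3G10610 at 1.73 ± 0.207, AT5G67510 at 1.63 ± 0.204 and AT3G56340 at 1.35 ± 0.168. Of 10 plastid ribosomal protein genes 7 were higher, among them AT5G65220 (1.39 ± 0.168) and AT1G29070 (1.22 ± 0.131), and AT5G24490 was lower at -1.82 ± 0.237. Adjusted over the list alone 8 were higher and 1 lower (median 0.71, adjusted p = 0.00193; adjusted p = 0.132 with an estimated correlation). Of 7 translation factor genes 2 rose, AT5G12110 by 3.41 ± 0.299 and EIF4A-2 by 0.85 ± 0.189 (adjusted p = 0.0724 for the list).

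Most measured members of the photosynthesis lists also moved up on polysomes at 4 h. The 6 photosystem genes (median 1.78, camera adjusted p = 1.6e-05, and 0.0371 with an estimated correlation) and the 3 antenna genes (median 1.46, adjusted p = 0.000875, and 0.0371 with an estimated correlation) were all higher. PSAN rose by 2.12 ± 0.213, PSBY by 1.92 ± 0.151 and PSB27 by 1.89 ± 0.175. Of the antenna genes, LHCB4.3, LHCB4.2 and LHCB4.1 rose by 2.11 ± 0.181, 1.46 ± 0.184 and 1.42 ± 0.188. RCA (1.75 ± 0.157) and SBPASE (1.70 ± 0.153) were higher of 3 Calvin cycle genes (median 1.70, adjusted p = 0.00439; adjusted p = 0.0676 with an estimated correlation). Of 4 photorespiration genes 3 rose, HPR by 1.69 ± 0.187, and AT1G80380 was lower at -0.91 (median 1.36, adjusted p = 0.025; adjusted p = 0.132 with an estimated correlation, and 0.062 in the fit of the compared arrays alone). PORB fell from 12790.5 ± 1071 to 2697 ± 809, a log2 change of -2.28 ± 0.205, while CHLM rose by 1.73 ± 0.178 and HEME1 by 1.34 ± 0.184.

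For the 9 chlorophyll genes on polysomes at 4 h, 5 were higher and 1 lower (median 0.45, adjusted p = 0.043; adjusted p = 0.132 with an estimated correlation). That list call ended without dark polysome replicate 3 (0.0529) or light 4 h polysome replicate 1 (0.0888), and under quantile normalization (0.0593), the stricter filter (0.0566), the added 32 (0.0526) and the fit of the compared arrays alone (0.0657). UGT78D2 rose by 4.15 ± 0.234 and UGT78D1 by 3.51 ± 0.435, and HYH by 4.18 ± 0.322 to 1622 ± 57.7.

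All 4 auxin genes were lower on polysomes at 4 h (median -2.23, camera adjusted p = 0.00101, and 0.0446 with an estimated correlation), with GH3.3 at -4.44 ± 0.625, IAA29 at -2.56 ± 0.266 and WES1 at -1.91 ± 0.22. All 4 starvation genes were lower (median -2.15, adjusted p = 7.95e-05; adjusted p = 0.0554 with an estimated correlation), MCCA at -3.51 ± 0.205 and AKINBETA1 at -2.20 ± 0.182. All 3 β-oxidation and glyoxylate genes were lower (median -0.94, adjusted p = 0.0127; adjusted p = 0.0554 with an estimated correlation): ICL at -1.49 ± 0.197, SDP1 at -0.94 ± 0.164 and AIM1 at -0.79 ± 0.172. Among genes with conserved upstream reading frames 1 of 5 was lower, bZIP44 (-1.0 ± 0.23; adjusted p = 0.677 for the list).

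Of the 69 chloroplast-encoded genes, 4 were higher and 1 lower on polysomes at 4 h (1 and 1 adjusted over the list alone; adjusted p = 0.107 for the list, 0.0479 with the block, which called 17 and 3; adjusted p = 0.744 with an estimated correlation and 0.535 with the block added). psbC rose by 1.27 ± 0.248 and psaA fell by 1.5 ± 0.273. The call of rbcL (0.75 ± 0.214) ended without dark polysome replicate 3 or light 4 h polysome replicate 2 (highest adjusted p = 0.0711). GI was at 0.62 ± 0.273 (adjusted p = 0.0868, and 0.0144 with the block). STZ rose by 1.49 ± 0.322 (adjusted p = 0.00108), and AT5G37670 was at 0.27 ± 0.447. SPCH rose by 2.35 ± 0.807 (adjusted p = 0.028), not called without dark polysome replicate 2 or 3 or light 4 h polysome replicate 1 or 3 (highest adjusted p = 0.105). PRL rose by 0.76 ± 0.28 (adjusted p = 0.0402), and its call ended without any of the 6 arrays compared (highest adjusted p = 0.163).

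**Figure D3:**
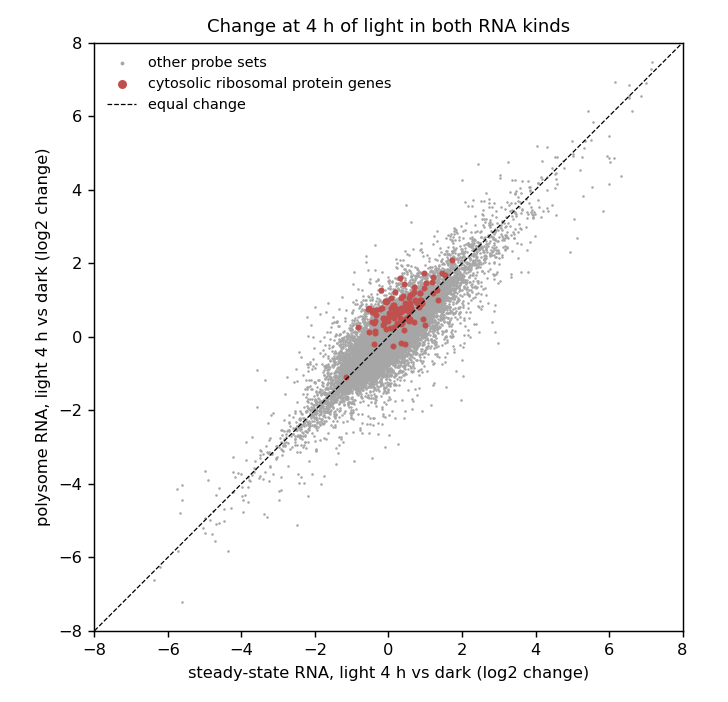
Log2 change after 4 h of light in polysome RNA (vertical axis) against that in steady-state RNA (horizontal axis) for 15922 probe sets, with 110 cytosolic ribosomal protein genes in red and a dashed line of equal change. The changes had a Pearson r of 0.866 across probe sets, and most of the ribosomal protein genes lie above the line (94 of 110 have a positive change in ratio).

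Changes at 4 h in the 2 kinds of RNA had a Pearson r of 0.866 and a Spearman rho of 0.793 across probe sets. With no filter r was 0.629 and with the stricter filter 0.914. The 2 sets of changes also shared calls. They shared 1962 higher calls, among them MSRB6, HYH and LHCB4.3, where 420.6 would be shared by independent lists. Lower calls in both were 2073, among them AT5G02580, MCCA and IAA29 (548.6 for independent lists). Of the 4058 called in both, 23 went in opposite directions. Here too the lists are not independent, as the 2 kinds of arrays of equal number deviated together (correlations of 0.108 to 0.419 at 4 h).

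Between 0.5 h and 4 h of light, 5397 probe sets changed in steady-state RNA (2611 higher, 2786 lower) and 5319 in polysome RNA (2317 higher, 3002 lower, all-probe-set median -0.101). With the replicate block these counts were 6764 and 6813. The balance of directions rests on the scaling. A common median gave 2535 higher and 2594 lower in polysome RNA (all-probe-set median -0.0397), and 2445 and 3013 in steady-state RNA. MSRB6 rose by 6.59 ± 0.331 in steady-state and 6.82 ± 0.331 in polysome RNA, and AT5G02580 was lower by -5.32 ± 0.521 and -5.23 ± 0.521. HYH (3.25 ± 0.322 and 3.68 ± 0.322) and UGT78D2 (2.61 ± 0.234 and 2.75 ± 0.234) were higher at 4 h than at 0.5 h. The median changes of the photosystem list were 1.49 and 1.56 and those of the starvation list -1.83 and -1.95, with camera adjusted p of 4.66e-05 and 1.2e-05, and 0.000188 and 6.44e-05. With an estimated correlation the adjusted p of the photosystem list was 0.0678 in steady-state (0.0296 with the block added) and 0.0496 in polysome RNA, and of the starvation list 0.0678 and 0.0696.

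Further lists differed between 0.5 h and 4 h of light. In polysome RNA the cytosolic ribosomal protein genes had a median of 0.60, with 63 higher and 0 lower (66 and 0 adjusted over the list alone; camera adjusted p = 4.59e-14; adjusted p = 0.112 with an estimated correlation). In steady-state RNA it was 0.23, with 39 higher and 6 lower (41 and 11 over the list alone; adjusted p = 0.00972; adjusted p = 0.521 with an estimated correlation). The auxin list was lower, at -1.04 in steady-state (adjusted p = 0.0309; adjusted p = 0.117 with an estimated correlation) and -1.38 in polysome RNA (adjusted p = 0.0332; adjusted p = 0.148 with an estimated correlation). Without light 0.5 h steady-state replicate 1 the steady-state calls of the auxin (0.0569), ribosomal protein (0.117), photorespiration (0.117) and β-oxidation (0.0745) lists ended. Without light 4 h steady-state replicate 2 they were at 0.051, 0.0573, 0.051 and 0.051. The photorespiration list was at 0.0531 without light 4 h steady-state replicate 1 and the β-oxidation list at 0.0656 without light 4 h steady-state replicate 3. These 2 calls also ended with the block (0.0846 and 0.0525), the stricter filter (0.0597 and 0.0643) and the compared arrays alone (0.0616 and 0.0584). That of β-oxidation also ended under quantile normalization (0.0521). The auxin call in polysome RNA ended without light 0.5 h polysome replicate 1 (0.0594) and with the stricter filter (0.0568), and that in steady-state RNA in the fit of the compared arrays alone (0.057).

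The chloroplast-encoded list had 7 of 69 genes higher, among them psbC and psbD, in steady-state RNA between 0.5 h and 4 h (median 0.19, camera adjusted p = 0.0472; adjusted p = 0.68 with an estimated correlation). Its median was -0.0503 without light 0.5 h steady-state replicate 1 (adjusted p = 0.841), and the call ended without light 4 h steady-state replicate 2 (0.195) or 3 (0.0656), under quantile normalization (0.0662) and with 32 added (0.0505). In polysome RNA 6 were higher and 1 lower (median 0.26, adjusted p = 0.0201; adjusted p = 0.674 with an estimated correlation), a call that ended without light 0.5 h polysome replicate 1 (0.264) or light 4 h polysome replicate 2 (0.062) and under quantile normalization (0.147).

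Polysome RNA was set against steady-state RNA of the same light condition to find transcripts with more or less signal on polysomes. As every array was scaled to the same level, such a ratio is relative to the other transcripts. The polysome RNA had also passed through a gradient, extraction and precipitation. A difference due to the preparation therefore cannot be told apart from polysome loading in these ratios. In the dark, the plastid ribosomal protein gene AT5G65220 was lower on polysomes, 2214 ± 153 against 6421 ± 424, a log2 ratio of -1.54 ± 0.168 (adjusted p = 3.19e-05). AT1G33470 was at -3.83 ± 0.455, AT3G50590 at -2.99 ± 0.448, the chlorophyll genes CHLM and AT1G74470 at -1.05 ± 0.178 and -0.92 ± 0.146, and LHCB4.2 at -0.83 ± 0.184. Higher on polysomes were AT5G15950 (1.07 ± 0.219) and ribosomal protein genes such as AT2G45710 (1.09 ± 0.226), AT1G80750 (1.05 ± 0.204) and AT3G47370 (0.84 ± 0.158). The largest positive ratios were those of AT3G03770 (2.80 ± 0.682), AT2G30540 (2.70 ± 0.668) and AT3G47980 (2.64 ± 0.715), all of low signal, and were 1.13, 1.28 and 1.35 with 32 added.

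The dark ratio was called for 1313 probe sets, 589 higher and 724 lower on polysomes (109 and 276 by 2-fold or more), and for 2738 with the block (1323 and 1415). Without single arrays it was 703 (dark steady-state replicate 2), 775 (dark steady-state replicate 3) and 622 (dark polysome replicate 1). The call of AT3G03770 ended without dark steady-state replicate 1 or 3 or polysome replicate 1 (highest adjusted p = 0.194), that of AT2G30540 without steady-state replicate 1 or polysome replicate 2 or 3 (0.15), and that of AT3G47980 without steady-state replicate 2 or 3 or polysome replicate 1 or 3 (0.118). SIZ1, a SUMO ligase gene at -3.09 ± 0.896 (adjusted p = 0.0369), lost it without any steady-state replicate or polysome replicate 1 (0.222), and STZ, at 1.36 ± 0.322, without polysome replicate 2 or 3 (0.169).

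Chlorophyll genes as a list were lower on polysomes in the dark, with 2 of 9 lower (median -0.44, camera adjusted p = 0.00586; adjusted p = 0.214 with an estimated correlation). Chloroplast-encoded genes were lower too, 11 of 69, or 12 adjusted over the list alone, including psaA (-1.87 ± 0.273), psbH (-1.58 ± 0.195) and ycf4 (-1.42 ± 0.195). Their list median was -0.14 (adjusted p = 0.00471; adjusted p = 0.753 with an estimated correlation). It was 0.12 without dark steady-state replicate 2 (adjusted p = 0.354), and the call ended without dark steady-state replicate 3 (0.0548) or dark polysome replicate 1 (0.108). Of the 110 cytosolic ribosomal protein genes 16 were higher and 5 lower (21 and 9 adjusted over the list alone; median 0.13, adjusted p = 0.294), the latter being AT5G28060, AT3G02080, AT3G14600, AT5G15200 and AT5G35530.

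After 0.5 h of light, AT5G10770 was higher on polysomes, 951 ± 140 against 232 ± 36.8, a log2 ratio of 2.04 ± 0.261 (adjusted p = 0.000117). AT5G65220 was again lower on polysomes (-1.14 ± 0.168), as were CHLM (-0.90 ± 0.178), psbE (-2.07 ± 0.291), ycf4 (-1.47) and psbH (-1.42 ± 0.195), and the ribosomal protein genes AT2G45710 (1.15 ± 0.226), AT1G80750 (1.03 ± 0.204) and AT4G34670 (0.88 ± 0.175) were higher. CLE26 (2.36 ± 0.659) and AT1G14580 (2.05 ± 0.565) on the higher side and AT2G14255 (-3.18 ± 0.848), AT5G24710 (-2.85 ± 0.793) and AT2G40860 (-2.54 ± 0.663) on the lower had weak signals. With 32 added they were at 1.12, 1.26, -1.66, -1.55 and -1.54. All 5 of these calls ended without light 0.5 h polysome replicate 2, those of CLE26, AT1G14580, AT2G14255 and AT5G24710 also without polysome replicate 1 and that of CLE26 without polysome replicate 3. Leaving out steady-state replicate 1 ended those of CLE26, AT2G14255 and AT5G24710, replicate 2 those of CLE26, AT2G40860 and AT5G24710, and replicate 3 all but that of CLE26 (highest adjusted p, 0.206 for CLE26).

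At 0.5 h the ratio was called for 1325 probe sets (644 higher, 681 lower; 141 and 262 by 2-fold or more), for 2944 with the block (1491 and 1453) and for 384 in the fit of the compared arrays alone. Single arrays weighed heavily here: the count was 2123 (1152 higher, 971 lower) without light 0.5 h steady-state replicate 1, 653 without steady-state replicate 2, 657 without steady-state replicate 3, 767 without polysome replicate 1 and 570 without polysome replicate 2. Of the 69 chloroplast-encoded genes 10 were lower and 1, psaB, higher (median -0.21, camera adjusted p = 0.0479; adjusted p = 0.83 with an estimated correlation), a call that ended without steady-state replicate 2 (0.526) or 3 (0.117) or polysome replicate 1 (0.662) or 3 (0.0742), under quantile normalization (0.0682) and in the fit of the compared arrays alone (0.0668). The chlorophyll list, with 3 of 9 genes lower, was at -0.20 (adjusted p = 0.0897), and the cytosolic ribosomal protein list, with 16 higher and 5 lower (AT2G40010, AT4G10450, AT5G60670, AT3G14600 and AT5G35530), at 0.13 (adjusted p = 0.196). Adjusted over the list alone these were 21 and 10, and with the block 28 and 15. GI was at 0.84 ± 0.273 (adjusted p = 0.0629, and 0.00509 with the block).

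After 4 h of light, 50 of 110 cytosolic ribosomal protein genes were higher on polysomes than in steady-state RNA and 1, AT3G11250, lower (60 and 5 adjusted over the list alone). Their median log2 ratio was 0.53 (camera adjusted p = 1.96e-18; adjusted p = 0.169 with an estimated correlation), with AT3G47370 at 2628 ± 399 on polysomes against 1078 ± 136, a log2 ratio of 1.28 ± 0.158, AT4G34670 at 1.29 ± 0.175 and AT2G27720 at 1.01 ± 0.151. Of 9 chlorophyll genes 7 were lower on polysomes (median -0.75, adjusted p = 6.05e-05, and 0.038 with an estimated correlation), among them CHLI2 (-1.08 ± 0.24), HEME1 (-1.03 ± 0.184) and HEMB1 (-0.75 ± 0.128). Of 7 translation factor genes 3 were lower (adjusted p = 0.352 for the list), AT4G20980 at -0.90 ± 0.208. AT5G10770 was higher at 2.41 ± 0.261 (adjusted p = 1.13e-05), and psaA lower, 549 ± 127 against 5544 ± 1519, at -3.32 ± 0.273.

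Of the 69 chloroplast-encoded genes 14 were lower on polysomes at 4 h (adjusted p = 0.128 for the list, 0.0421 with the block and 0.00708 under quantile normalization; adjusted p = 0.897 with an estimated correlation and 0.577 with the block added), including psbH (-1.76 ± 0.195) and ycf4 (-1.61). AT2G14255 (-4.26 ± 0.848), AT1G32810 (-4.24 ± 0.636) and SIZ1 (-4.10 ± 0.896) were lower too, or -2.29, -2.15 and -2.65 with 32 added. AT5G04310 (2.15 ± 0.571) was not called without light 4 h polysome replicate 1 or steady-state replicate 3 (highest adjusted p = 0.0768), nor AT4G14840 (2.14 ± 0.565) without steady-state replicate 2 (0.0931 at most over all settings); with 32 added they were at 1.26 and 1.12.

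Altogether 2133 probe sets had a called ratio at 4 h, 884 higher and 1249 lower (184 and 470 by 2-fold or more), and 3677 with the block (1535 and 2142). When the arrays were shifted to a common median the split became 1178 higher and 893 lower, so the balance of directions rests on the scaling, against an all-probe-set median of -0.0595. The count was 1374 without light 4 h steady-state replicate 2, 1381 without steady-state replicate 3 and 1257 without polysome replicate 2.

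**Figure D4:**
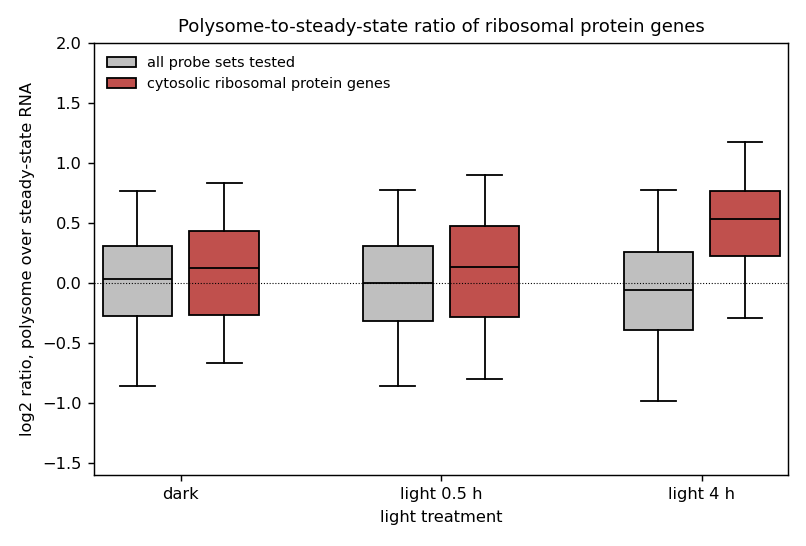
Log2 ratio of polysome over steady-state signal (vertical axis) of 110 cytosolic ribosomal protein genes (red) and all 15922 probe sets (grey) in the dark and after 0.5 h and 4 h of light; boxes span the quartiles, lines are medians and whiskers reach the 5th and 95th percentiles. The median of the ribosomal protein genes is 0.13 in the dark, 0.13 at 0.5 h and 0.53 at 4 h.

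The ratios of the 3 light conditions, taken from separate arrays, had a Pearson r across probe sets of 0.64 (dark and 0.5 h), 0.542 (dark and 4 h) and 0.536 (0.5 h and 4 h). A set of 232 probe sets was higher on polysomes in all 3 conditions, where independent lists would share 1.32. Another 285 were lower in all 3 (2.43 for independent lists). The chloroplast genes psbH and ycf4 belonged to the latter. An effect of the RNA preparation could be shared by all 3 conditions too. Arrays of equal number also deviated together across light conditions, so these lists are not independent.

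The question at the centre of the series, whether light alters polysome loading beyond the change in transcript level, was tested as the difference between the polysome and the steady-state response. After 4 h, AT2G26500, which encodes the PetM subunit of the cytochrome b6f complex, rose by 1.69 ± 0.181 in log2 ratio (adjusted p = 0.00021), reaching 24217 ± 1767 on polysomes and 18573 ± 1355 in steady-state RNA. AT5G65220, low on polysomes in the dark, rose by 1.56 ± 0.238 (adjusted p = 0.00483), to 5829 ± 676 and 5719 ± 405. Ratios also rose for AT2G29180 (1.72 ± 0.305), AT1G53120 (1.70 ± 0.345), AT1G73120 (1.69 ± 0.326), AT4G38490 (1.65 ± 0.308), AT5G05710 (1.63 ± 0.299), the ribosomal protein genes AT3G02080 (1.32 ± 0.276) and AT3G14600 (1.08 ± 0.22), and the plastid ribosomal protein gene AT4G17560 (1.04 ± 0.215). ATATH8 had the one named decrease, at -1.49 ± 0.296 (adjusted p = 0.0306).

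The 4 h ratio change was called for 58 probe sets, 53 higher and 5 lower, each by 2-fold or more, and for 300 with the replicate block (221 and 79). The count was 13 with no intensity trend, 88 with a common median and 259 with replicate-wise ratios. Across all probe sets the median change was -0.101. It was 0.0029 with a common median and -0.0312 under quantile normalization, so its size and sign rest on the scaling. Leaving out any of 10 of the 12 arrays, which also leaves fewer arrays in the fit, clearly lowered the count. It was 16 and 12 without dark steady-state replicates 2 and 3, and 32 and 14 without dark polysome replicates 2 and 3. Without light 4 h steady-state replicates 1, 2 and 3 it was 17, 32 and 31, and without light 4 h polysome replicates 1, 2 and 3 it was 23, 15 and 38. AT2G26500 and AT5G65220 were called in all of these, while each of the 9 other named genes lost its call without at least 5 of the 12 arrays (highest adjusted p between 0.07 for AT2G29180 and 0.157 for AT3G02080).

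As a list, the cytosolic ribosomal protein genes gained polysome ratio after 4 h of light. Their median change was 0.38, or 0.48 above the median of all probe sets, with a positive change for 94 of 110 genes and 2 called, 17 adjusted over the list alone and 12 with the block (camera adjusted p = 1.95e-18; adjusted p = 0.203 with an estimated correlation). Plastid ribosomal protein genes had a median change of 0.25, with 2 of 10 called and 3 adjusted over the list alone (adjusted p = 0.000114; adjusted p = 0.203 with an estimated correlation). The chlorophyll list was at -0.53 with 0 of 9 called (adjusted p = 0.281). LHCB4.1 was at 0.70 (adjusted p = 0.428), and AT5G19510 at 0.92 (adjusted p = 0.0957, and 0.0229 with the block).

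After 0.5 h of light, 0 probe sets had a called change in ratio by limma, with 257 at an unadjusted p under the threshold, and 0 and 569 with the replicate block. The plastid ribosomal protein list had a median change of 0.12 with 0 of 10 genes called and 1 higher when adjusted over the list alone (camera adjusted p = 0.00655; adjusted p = 0.931 with an estimated correlation). That call ended without dark steady-state replicate 2 (0.0782) or 3 (0.0721), light 0.5 h steady-state replicate 1 (0.395) or light 0.5 h polysome replicate 2 (0.136). The cytosolic ribosomal protein list was at 0.015 (adjusted p = 0.849), and STZ at -0.27 ± 0.455.

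Some lists could not be read. HY5, TT4, LHCB1, ELIP1, PORA and PHYA, named beforehand as genes to report, have no probe set that lists them alone. The photoreceptor and repressor, 20S proteasome, root-enriched, vascular and epidermis lists had 0 measured genes, and 7 of the 26 lists had 1 or 2. Of the 15922 tested probe sets, 6808 list no gene in the annotation used. A gene that was not measured here may therefore still have a probe set on the arrays. The mitochondrion-encoded list could not be matched to the arrays. The gene identifiers of the reference table differ there from those of the array annotation. Probe sets of mitochondrial genes such as nad1 and nad4 are on the arrays. The markers MUTE, EXPA7 and EXPA18 lay below the signal filter, with group means of up to 48.9 for MUTE, 21 for EXPA7 and 53.3 for EXPA18.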

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

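The tests of a common shift of scale, strong signal and single replicate numbers, the test of weak probe sets and the splits that move labels separately were written before their values were seen. The array-scaling test of the direction of the 4 h ratio calls and the splits that move both arrays of a number together were chosen only after the result was seen.

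Responses at 4 h and 0.5 h of light differed from each other, tested as the contrast of 4 h against 0.5 h. In steady-state RNA 5397 probe sets differed and in polysome RNA 5319. The list medians that differed in steady-state RNA were 0.682 for antenna, 1.49 for photosystem, 0.799 for chlorophyll, 1.91 for Calvin cycle, 0.99 for photorespiration, -1.04 for auxin, 0.229 for cytosolic ribosomal protein, -0.684 for β-oxidation and glyoxylate, -1.83 for starvation and 0.187 for chloroplast-encoded genes. With an estimated correlation none of these 10 lists passed (adjusted p = 0.0678 for antenna, photosystem, chlorophyll, Calvin cycle and starvation, 0.0959 for β-oxidation, 0.117 for auxin, 0.235 for photorespiration, 0.521 for ribosomal protein and 0.68 for chloroplast-encoded genes). With the block added to it, photosystem did (0.0296). With the block and the preset correlation, photorespiration (0.0846) and β-oxidation (0.0525) did not. In polysome RNA they were 1.09 for antenna, 1.56 for photosystem, 1.69 for Calvin cycle, 1.2 for photorespiration, -1.38 for auxin, 0.598 for cytosolic and 0.651 for plastid ribosomal protein, -0.887 for β-oxidation and glyoxylate, -1.95 for starvation and 0.257 for chloroplast-encoded genes. With an estimated correlation antenna and photosystem passed (adjusted p = 0.0496 each), and the others did not (0.0696 for β-oxidation and starvation, 0.112 for Calvin cycle and cytosolic ribosomal protein, 0.148 for auxin, 0.157 for photorespiration and plastid ribosomal protein, 0.674 for chloroplast-encoded genes). The photorespiration call also ended in the fit of the compared arrays alone (0.066). Named genes that differed in steady-state RNA were MSRB6 6.588, AT1G60590 6.40, THI2.2 5.694, AT5G02580 -5.319, AT4G25580 -5.276 and AT2G34020 -5.119. In polysome RNA they were AT1G60590 8.455, AT5G42760 6.832, MSRB6 6.818, AT2G34020 -5.442, AT5G02580 -5.23 and AT3G50120 -4.711. With 32 added to each signal, AT1G60590 in polysome RNA was at 5.65 and AT3G50120 at -1.93.

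Steady-state and polysome RNA also responded differently to 4 h of light, tested as the change in ratio: 58 probe sets differed. The genes were AT2G29180 1.716, AT1G53120 1.70, AT1G73120 1.691, AT2G26500 1.686, AT4G38490 1.646, AT5G05710 1.629, ATATH8 -1.494, AT3G14600 1.078, AT3G02080 1.32, AT5G65220 1.559 and AT4G17560 1.044. The lists were cytosolic ribosomal protein genes, 0.375, and plastid ribosomal protein genes, 0.254, and at 0.5 h the plastid list, 0.115. With an estimated correlation none of the 3 passed (adjusted p = 0.203, 0.203 and 0.931), and the 0.5 h call also ended without dark steady-state replicate 2 (0.0782) or 3 (0.0721), light 0.5 h steady-state replicate 1 (0.395) or light 0.5 h polysome replicate 2 (0.136).

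The gain in polysome ratio of cytosolic ribosomal protein genes at 4 h was weighed against 3 technical explanations. Quantile normalization left the list median 0.369 above that of all probe sets, which argues against array scaling; a common median shifts all probe sets of an array alike and tests nothing here. Among 10000 lists matched on mean expression the middle median was -0.0408 and the highest 0.112, against 0.375 for this list (percentile 100). That argues against strong signal alone as the source. The matched lists were drawn from unrelated probe sets, so the percentile does not measure chance for genes that move together. The replicate-wise difference was at least 0.388, which argues against a single replicate number. Transcript length was not tested and stays open, and light itself, the biological explanation of the design, cannot be told apart from other differences between the groups.

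The excess of higher over lower calls in the 4 h ratio change (53 against 5) was weighed against 2 explanations. The share of higher calls was 91.4% as deposited, 95.5% with a common median and 92.4% under quantile normalization. Both settings raised the median change of all probe sets, from -0.101 to 0.0029 and -0.0312. They could therefore hardly lower that share, and they do not decide about the scaling of the arrays. Of the 53 higher calls, 0% lay among the probe sets of lowest mean signal (below the lower quartile). This cannot decide about weak probe sets, since their errors are large and they can hardly be called. With no filter, the standard error of this change ran from 0.717 for FMA to 1.56 for MUTE among the weak markers. The median over tested probe sets was 0.352. With the block the split was 221 and 79, so the size of the excess depends on the fit. No biological explanation was tested.

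Counts of calls were set against other splits of the same arrays. In each of the 9 comparisons of 3 arrays against 3, 1 of 10 splits, the real one, gave as many calls, and the highest other count was 11, in steady-state RNA at 0.5 h, against 1 or 0 in the others; with 10 splits no share under 0.1 is possible. For the ratio change at 0.5 h the real count was 0, so all splits gave as many whatever the data: 100 of 100 drawn with labels moved array by array (highest other 440), and 10 of 10 with both arrays of a number moved together (highest other 0). At 4 h, 12 of 100 splits with labels moved array by array gave as many calls as the real 58 (highest other 7526). Such splits put the effect of light itself into the contrast, a structure of the samples, and part the paired arrays, so they say nothing about chance. With both arrays of a number moved together, 1 of 10 gave as many as the real 259 (highest other 0), and 10 splits are too few for a share under 0.05.

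Groups of 3 arrays were not tested for outlying samples.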

How the results depend on the processing

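Replicate-wise ratios, the block with an estimated correlation and leave-one-out for the correlations were chosen after the data were seen. With the replicate block the counts of calls were 409 (steady-state, 0.5 h), 357 (polysome, 0.5 h), 2738, 2944 and 3677 (polysome against steady-state RNA in the dark, at 0.5 h and at 4 h) and 300 (4 h ratio change). They were 6756 and 7115 for 4 h against dark in steady-state and polysome RNA, and 6764 and 6813 for 4 h against 0.5 h. Apart from the calls given beside their results, the 3 list calls that ended (β-oxidation in steady-state RNA at 4 h, 0.0641, and at 4 h against 0.5 h, 0.0525, and photorespiration there, 0.0846) and 15 gene calls gained, the block changed no other call of a list or named gene. The compared arrays alone gave 88 (steady-state, 0.5 h) and 384 (polysome against steady-state RNA, 0.5 h). The 4 h ratio change called 88 with a common median, 13 with no intensity trend and 259 with replicate-wise ratios. The correlation of steady-state and polysome changes was 0.131, 0.663 and 0.536 at 0.5 h and 0.629, 0.914 and 0.896 at 4 h with no filter, the stricter filter and 32 added. It was thus lower with the weakest probe sets included and higher with more of them left out. Leaving out 1 array gave 147 to 389 calls (steady-state, 0.5 h), 622 to 1299, 570 to 2123 and 1257 to 1743 (polysome against steady-state RNA in the dark, at 0.5 h and at 4 h), 12 to 73 (4 h ratio change) and correlations of 0.328 to 0.409 and 0.836 to 0.859. The chloroplast-encoded list reversed: -0.589 to 0.122 in the dark ratio (0.122 without dark steady-state replicate 2), -0.422 to 0.139 in steady-state RNA at 0.5 h (1.17e-06 without dark steady-state replicate 3, 0.139 without light 0.5 h steady-state replicate 1) and -0.0503 to 0.402 at 4 h against 0.5 h. The causes were not tested. Most of the list calls, 44 of them, ended with an estimated correlation, so the p-values of these rest on the preset one. Among them was the call of the cytosolic ribosomal protein genes in the 4 h ratio change. Of the 143 list tests, the other 99, called or not, stayed on the same side of the threshold. Of the named-gene values, 260 lost and 7 gained a call when 1 array was left out, and 2547, called or not, stayed on the same side of the threshold. Low signals limit all folds from near the floor.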

Other observations

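The families below were grouped by gene symbol and chosen only after the data were seen, with no test written beforehand. After 4 h of light the expansin (EXPA) family was lower, with 4 of 6 members lower in steady-state RNA (median -1.13, camera adjusted p = 0.026; adjusted p = 0.276 with an estimated correlation) and 3 of 6 in polysome RNA (median -1.02, adjusted p = 0.046; adjusted p = 0.282 with an estimated correlation). Members of the CRR family, named for chlororespiratory reduction, were higher, 4 of 5 in each kind of RNA (medians 1.93 and 1.18, adjusted p = 0.026 and 0.0431; adjusted p = 0.572 and 0.282 with an estimated correlation).

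On polysomes against steady-state RNA at 4 h, the TET family was lower (5 of 9 members, median -0.84, adjusted p = 0.00242; adjusted p = 0.0877 with an estimated correlation). The VPS family was higher (5 of 9, median 0.43, adjusted p = 0.0104; adjusted p = 0.0877 with an estimated correlation), as was NRPB (3 of 6, median 0.79, adjusted p = 0.0145; adjusted p = 0.0895 with an estimated correlation). Mitochondrial NAD genes (6 measured) had a median of -0.739 in this ratio, with 1 lower (camera adjusted p = 0.289, and 0.905 with an estimated correlation). Against dark, their medians at 4 h were 0.0086 in steady-state and -0.028 in polysome RNA (adjusted p = 0.857 and 0.986, and 0.893 and 0.99 with an estimated correlation). In all, 39 families were tested.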
